A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

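Nucleosome positions were measured by MNase-seq, in which micrococcal nuclease digests the DNA between nucleosomes and the protected fragments are sequenced. Per the labels, asynchronous cells of the W303 background of budding yeast (Saccharomyces cerevisiae) were grown in YPD, a rich glucose medium, at 25 °C. The genotypes were wild type, sir2, rpd3 and rpd3 sir2, with 1 library each. Sir2 and Rpd3 are histone deacetylases. Genotypes were taken from the labels alone.

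Per the submitters' processing notes, CASAVA 1.8.2 and Bowtie2 2.1.0 were used; the notes give no role for either. The genome build of the aligned reads was sacCer3, per the labels. The authors deposited 1 list of aligned reads per library, with other values than counts in its position columns: the start and end of each read. The deposited lists also hold a score for each read, the mapping quality, between 0 and 42. No mapping quality or duplicate filter was visible in the values, nothing was pooled, and nearly all reads were 51 bp long and single-end. The authors also deposited 1 list of nucleosome positions on an rDNA sequence per library, as intervals of 1 bp in other units than counts (a position in bp), with no score or height. The caller of these positions, its settings and the rDNA sequence are not given in the sources used here.

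The rest was computed from these lists. Each read was turned into 1 nucleosome midpoint (dyad), 73 bp downstream of its 5′ end. The distance between the forward and reverse strand profiles was 135, 134, 138 and 136 bp in the wild type, sir2, rpd3 and rpd3 sir2 libraries. Genes and origins were taken from the RefSeq annotation of the same yeast assembly. Dyads were scaled to each library's total on the nuclear chromosomes outside the rDNA, and log2 ratios used a pseudocount of 0.5 dyads. Intervals are 95% intervals from the counts: exact Poisson intervals for a level, exact Clopper-Pearson intervals for a share, and intervals of the ratio of 2 counts for a log2 ratio. They cover counting error only, since reads without molecular identifiers are not independent molecules. Between 30.1% and 34.5% of reads shared start, end and strand with another read of the same library.

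With 1 library per genotype there was no test between genotypes and no p-value. Each mutation was instead compared in both backgrounds. The sir2 contrasts were labelled sir2 over wild type and labelled rpd3 sir2 over rpd3. The rpd3 contrasts were rpd3 over wild type and labelled rpd3 sir2 over labelled sir2. The 2 contrasts of a mutation have no library in common. A promoter or window was counted as different when both ratios went the same way, were at least 1.5-fold and had intervals that excluded 1; for rDNA bins the first 2 conditions alone were used. As a reference for differences between libraries, the same thresholds were applied to promoters whose 2 sir2 contrasts went opposite ways (the crossed contrast). It cannot show differences that both libraries labelled sir2 share, and it is no reference for the rpd3 contrasts. Promoters were the 200 bp upstream of the coding start of 6008 genes, and 3962 had the required mean of at least 20 dyads per library. The libraries held a mean of 57.7, 69.1, 54.9 and 56.5 dyads per 200 bp, in the order given above.

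The rDNA profile used reads on the 2 repeat copies in the reference, added together over the unit of 9137 bp and scaled to the repeat's own total, in bins of 50 bp. The deposited rDNA positions were placed on chromosome XII by the shift and strand at which they fell best on maxima of dyad density. This map was inferred from the data: the opposite strand gave a score of 1.09, against 0.548 for its next best shift and 0.530 for the other strand. Positions of different libraries were matched 1 to 1 within 40 bp. Profiles at gene starts covered 3330 genes in bins of 10 bp, with intervals from 200 resamplings of genes.

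Gene lists were fixed before the data were examined, as were the contrasts, thresholds, origin lists and most alternatives. The median of each list over both backgrounds was placed among 10000 random lists of the same size, matched on mean occupancy. Of 20 lists, 19 could be placed; the list of silent mating loci, with 2 measured members, was given by gene. Named promoters were the 10 highest and 10 lowest of each mutation by the smaller of the 2 absolute log2 ratios, among promoters whose ratios went the same way, with a mean of at least 50 dyads and at most 10% of reads of mapping quality under 10. SIR2, RPD3, the silent mating loci and the rDNA features were always named. The 2 highest and 2 lowest members of each list described were named too. So were the 3 highest and 3 lowest origins among those with a mean of at least 50 dyads. A gene outside this rule was chosen after its values were seen, and the text says so.

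In simulated data on the 3962 promoters, with 50 promoters changed at each size, the sir2 contrasts recovered 10% of 1.5-fold changes, 58% of 2-fold changes, 96% of 3-fold changes and 98% of 4-fold changes. Of 3762 unchanged promoters, 3 were called. For the rpd3 contrasts the shares were 18%, 62%, 92% and 96%, and 2 of 3762 unchanged promoters were called. These simulated counts held Poisson counting error only, without identical reads or other differences between libraries. The shares and the calls of unchanged promoters therefore need not hold for the real libraries. All 34 simulated rDNA positions, moved by up to 29 bp, were matched to the position they came from. They were evenly spaced, too far apart for a match within 40 bp to confuse them. This outcome was therefore fixed in advance and does not measure the matching on the real lists.

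Alternatives covered the match distance, duplicate reads, bin and window sizes, the dyad offset, the scaling, the minimum, a correction for GC content and the distance from chromosome ends. Alternatives added after the data were seen were a dyad offset of 67 bp, leaving out repeated sequence and copy number segments, a minimum of 20 dyads for origins, leaving out the origins of the CUP1 array, averaging the ratios of coverage bins, and resampling the same genes in both libraries. The comparison of listed shifts with shifts of the dyad density maximum at the positions described was also added then. The marker genes, the copy number segments, the stretch beside HML, the NTS1 stretch, the split of HMR and a scan of 500-bp windows were also chosen after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.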

Results

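Nucleosome maps were compared between wild type yeast and cells labelled sir2, rpd3 and rpd3 sir2, in 1 MNase-seq library per genotype. By its title, the series concerns histone deacetylases that act at the ribosomal DNA and affect the replication program. The libraries held 3918166, 4532495, 3682176 and 3694858 aligned reads, in that order. Outside the rDNA, 3475280, 4162455, 3308509 and 3407100 nucleosome midpoints (dyads) were placed on the nuclear chromosomes. No genotype was repeated, so each difference is between libraries and has no replicate check. It is given with a 95% counting interval, and each mutation was read in both backgrounds.

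RPD3, on chromosome XIV from 18001 to 19302, was missing from both libraries whose labels name it. Its coding sequence held 420 dyads in wild type, 506 in the library labelled sir2, 40 in rpd3 and 33 in the library labelled rpd3 sir2. From 18001 to 19200 the counts were 384, 472, 3 and 4. SIR2, on chromosome IV from 376757 to 378445, was present in every library, with 461, 550, 457 and 409 dyads. This goes against a deletion of SIR2 in the libraries labelled sir2 and rpd3 sir2, whose labels do not state the kind of allele. Relative to the genome mean these were 0.947, 0.943, 0.986 and 0.857, so the library labelled sir2 held 99.6% of the wild type level and the library labelled rpd3 sir2 90.5%. At each of its 1689 positions, at least 5 reads of these 2 libraries together, and at least 1 of each, ran across with a margin of 5 bp. SIR1, SIR3, SIR4, HST1 and HST2 also had reads in every library. Both libraries are therefore called by their labels, and every direction given for a sir2 contrast rests on a label that the SIR2 reads do not bear out.

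The 2 libraries labelled sir2 also shared large differences in dyads at single stretches, described after they were seen. Several, called copy number segments below, were picked by read counts, but no undigested DNA was analysed to measure copies. A stretch beside and within HML, the silent copy of the alpha mating genes (chromosome III, 14101 to 15400), held 198 dyads in wild type, 0 in the library labelled sir2, 227 in rpd3 and 3 in the library labelled rpd3 sir2. HIS3 and LEU2, biosynthetic genes often used as selection markers, were at 2.74 and 2.76 times the genome mean in the library labelled sir2 and at 2.66 and 2.95 in that labelled rpd3 sir2. In wild type they were at 1.496 and 1.46, and in rpd3 at 1.396 and 1.28. URA3, another marker, was at 6.51 and 7.03 times the mean in wild type and rpd3 and at 3.90 and 2.83 in the libraries labelled sir2 and rpd3 sir2. Against wild type, the left end of chromosome I (2001 to 12000) was higher in both libraries, at log2 0.93 and 1.11. Its right end (220001 to 230000) was lower, at −1.12 and −1.11. Stretches of chromosome VIII from 540001 to 544000 (−0.84 and −0.76) and from 550001 to 556000 (−0.92 and −0.83) were lower too. A stretch of chromosome XIII that holds NUP116, CSM3 and ERB1 (362001 to 372000) was higher in the library labelled sir2 alone, at log2 0.99 (0.93 to 1.06). Whole chromosomes lay between 0.978 and 1.04 times the wild type level.

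**Figure D1:**
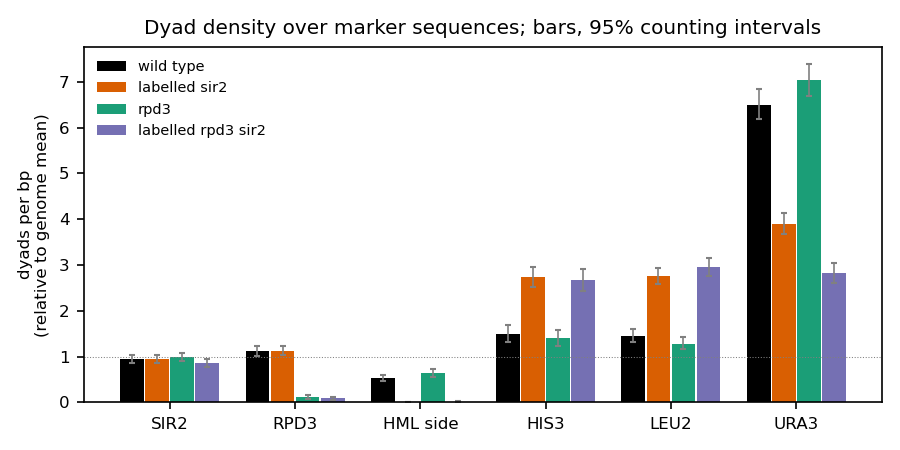
Bars give dyads per bp relative to the genome mean (y axis, from 0) over 6 sequences (x axis) in the 4 libraries, with 95% counting intervals; the dotted line marks 1. SIR2 lies near 1 in every library (0.947, 0.943, 0.986 and 0.857), RPD3 at 0.112 and 0.0897 in both rpd3 libraries, and HIS3 at 2.74 and 2.66 in the libraries labelled sir2 and rpd3 sir2.

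The rDNA, the array of ribosomal RNA gene repeats on chromosome XII, took a smaller share of nuclear reads in the libraries labelled sir2. The share was 11.3% (95% Clopper-Pearson interval 11.2 to 11.3) in wild type and 8.06% (8.04 to 8.09) in the library labelled sir2. In rpd3 it was 10.1% (10.1 to 10.2), and in the library labelled rpd3 sir2 7.76% (7.73 to 7.79). Relative to single-copy sequence, these shares correspond to 168, 116, 149 and 111 apparent copies of the repeat. The share follows the number of repeats and their sensitivity to the nuclease together. With identical reads collapsed, it was 1.098%, 0.925%, 1.12% and 1.01%.

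The question at the rDNA was whether nucleosomes take other positions without the deacetylases. The deposited lists placed 36 nucleosomes in the repeat in wild type, 32 in the library labelled sir2, 33 in rpd3 and 31 in the library labelled rpd3 sir2. The 2 libraries labelled sir2 had nearly the same list: 30 positions of the library labelled rpd3 sir2 matched one of the library labelled sir2, with a median distance of 1 bp. Of the wild type positions, 31 had a match in the library labelled sir2 (median distance 7 bp), 27 in rpd3 (2 bp) and 30 in that labelled rpd3 sir2 (7.5 bp). The library labelled rpd3 sir2 matched rpd3 at 24 positions, with a median of 15 bp. Among the 29 wild type positions with a match in both libraries labelled sir2, 8 lay at least 15 bp away in the library labelled sir2. Of these 8, 7 lay at least 10 bp away in the same direction in the library labelled rpd3 sir2.

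Of these 7 positions, 5 lie in the 18S gene and 2 in NTS2, but most shifts were smaller in the reads than in the lists. The shift of the dyad density maximum was within 10 bp of the listed shift at 2 of the 7 in the library labelled sir2 and at 3 in that labelled rpd3 sir2. The position at 458967 in NTS2, the spacer between the 5S and 35S genes, borders the replication origin ARS1200-1 (458991 to 459097) in the copy of the repeat used here. In the lists it lay 23 bp closer to the origin in both libraries labelled sir2, while the density maximum lay 11 and 9 bp closer; it had no match in rpd3. In the 18S gene, positions 375, 538 and 705 of the list (456710, 456547 and 456380 on the chromosome) had shifts of −21, −18 and −25 bp in the library labelled sir2. In the library labelled rpd3 sir2 the shifts were −20, −18 and −26 bp. The density maxima there had shifts of −5, −12 and −9 bp, and of −2, −9 and −8 bp. At 457496, also in the 18S gene, list and density came closest, with −19 and −24 bp in the library labelled sir2 and −17 and −20 bp in that labelled rpd3 sir2. Negative shifts point against the transcription of the 35S gene. In NTS1, the spacer on the other side of the 5S gene, the wild type position at 460069 had no match in either library labelled sir2 and a match in rpd3. Unmatched positions of rpd3 lay at 457987, 458162 and 458351 in the 5′ external transcribed spacer and at 456051 in the 18S gene. Others lay at 458494 in NTS2 and at 460604 in NTS1. In windows around the external spacer and 18S positions, rpd3 held 1.83%, 1.51%, 1.58% and 1.76% of the repeat's dyads. Wild type held 1.92%, 1.68%, 1.57% and 1.99% there. At NTS2 and NTS1 rpd3 held more, 1.39% and 0.694% against 0.957% and 0.485%. In 50-bp bins, the external spacer and 18S positions held 0.835%, 0.645%, 0.827% and 0.834% in rpd3. In wild type these bins held 0.539%, 0.548%, 0.404% and 0.914%. Over all positions, shifts of the density maximum were within 10 bp of the listed shift at 22 of 31, 24 of 27 and 23 of 30 positions in the libraries labelled sir2, rpd3 and rpd3 sir2.

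**Figure D2:**
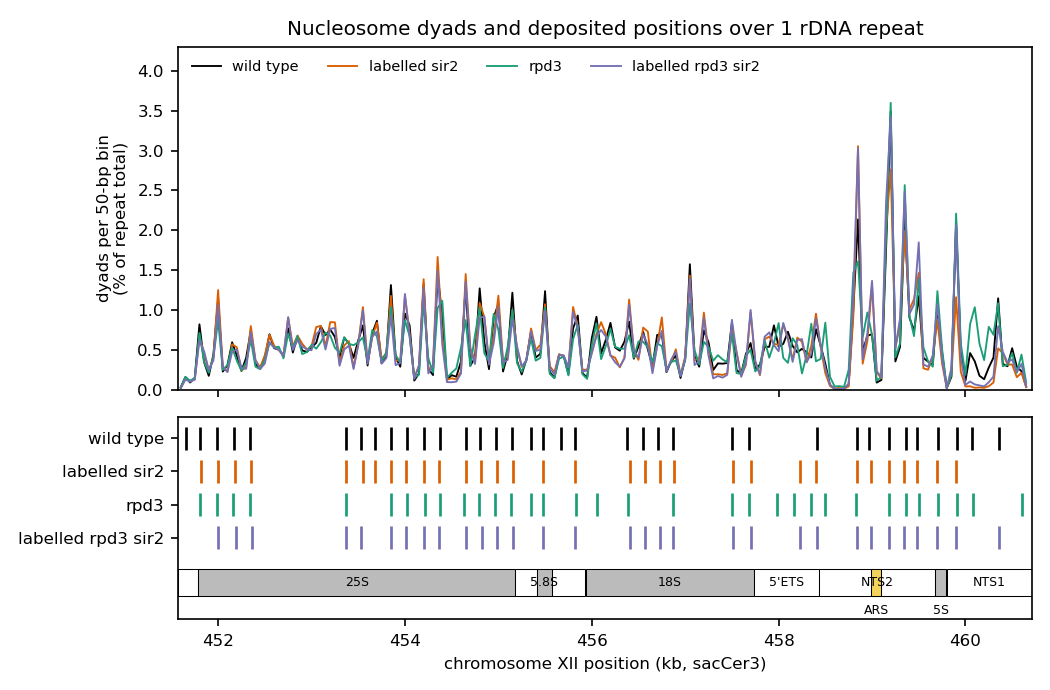
Lines give dyads per 50-bp bin as a percent of the repeat's total (y axis) along 1 rDNA repeat (x axis, kb of chromosome XII) in the 4 libraries, with the deposited positions as ticks and the annotated features under them. The lists hold 36, 32, 33 and 31 positions, and the largest peaks lie in NTS2.

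Dyad density within the repeat separated the libraries most in the spacers. NTS1 held 7.53% of the repeat's dyads in wild type, 3.90% in the library labelled sir2, 10.4% in rpd3 and 5.92% in the library labelled rpd3 sir2. The longest run of bins that passed the thresholds in the sir2 contrasts was a 350-bp stretch of NTS1 (459975 to 460324), 179 bp from the 5S gene. It held 1.91%, 0.286%, 4.47% and 0.579% of the repeat's dyads. This was 6.67-fold lower (6.26 to 7.12) in the library labelled sir2 than in wild type, and 7.72-fold lower (7.34 to 8.13) in the library labelled rpd3 sir2 than in rpd3. The same stretch was the longest run in the rpd3 contrasts, in the other direction: 2.34-fold higher (2.28 to 2.40) in rpd3 than in wild type and 2.02-fold higher (1.87 to 2.19) in the library labelled rpd3 sir2 than in that labelled sir2. At ARS1200-1 the share was 0.525% in wild type and 0.554% in rpd3, and 1.16% and 1.17% in the libraries labelled sir2 and rpd3 sir2. In the window around the bordering wild type position at 458967 the shares differed less, at 1.77%, 2.27%, 2.19% and 2.48%. A shift of that nucleosome across the edge of the origin cannot be told apart from a gain of dyads there. NTS2 held 18.4%, 20.1%, 20.7% and 22.6%, and the 25S gene 38.9%, 40.3%, 36.5% and 36.9%.

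Over the 182 bins of the repeat, 10 were higher and 16 lower in both sir2 contrasts, 7 of the lower bins in NTS1. In both rpd3 contrasts 9 bins were higher, 8 of them in NTS1, and 0 were lower. Log2 ratios of the 2 sir2 contrasts had a Pearson correlation of 0.81 across bins, and those of the rpd3 contrasts 0.29. Bins are not independent replicates. The profile of the library labelled sir2 was closest to that labelled rpd3 sir2 (r = 0.971, against 0.905 with wild type and 0.776 with rpd3).

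**Figure D3:**
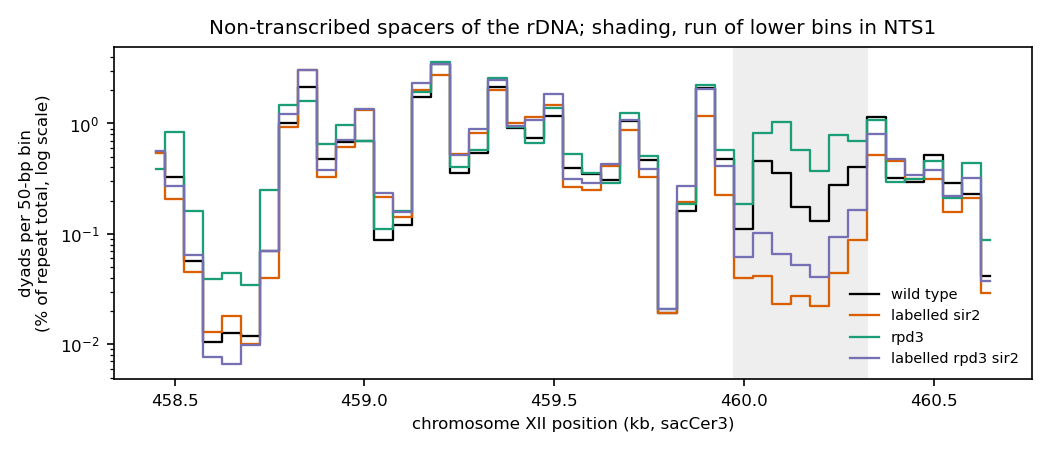
Steps give dyads per 50-bp bin as a percent of the repeat's total (y axis, log scale) across NTS2, the 5S gene and NTS1 (x axis, kb of chromosome XII) in the 4 libraries. The shaded 350-bp stretch held 1.91% in wild type, 0.286% in the library labelled sir2, 4.47% in rpd3 and 0.579% in the library labelled rpd3 sir2.

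Gene starts had the same layout in the 4 libraries, with a slightly less depleted region upstream in the rpd3 contrasts. Averaged over 3330 genes, dyad density upstream of the coding start had a minimum of 0.308 times the genome mean (0.289 to 0.325 over resampled genes) in wild type and 0.317 (0.300 to 0.334) in the library labelled sir2. It was 0.337 (0.315 to 0.354) in rpd3 and 0.334 (0.315 to 0.351) in the library labelled rpd3 sir2. With the same genes resampled in both libraries, a comparison added after the data were seen, the minimum was higher by 0.029 (0.020 to 0.036) in rpd3 than in wild type and by 0.017 (0.010 to 0.025) in the library labelled rpd3 sir2 than in that labelled sir2. In the sir2 contrasts the differences were 0.0089 (0.0024 to 0.016) and −0.0028 (−0.0094 to 0.0074). The mean from −250 to −1 was higher by 0.019 (0.013 to 0.023) and 0.024 (0.020 to 0.029) in the rpd3 contrasts, and by 0.0040 (−0.00014 to 0.0077) and 0.0095 (0.0055 to 0.014) in the sir2 contrasts. The first nucleosome peak lay near 13 bp downstream of the coding start in each library, at a height of 1.39, 1.39, 1.397 and 1.43 times the genome mean. Spacing between nucleosomes +1 and +4 was 162.1 bp in wild type and 162.9, 162.8 and 163.0 bp in the libraries labelled sir2, rpd3 and rpd3 sir2.

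At promoters, the sir2 contrasts differed at few genes, among them HMRA1 and HMRA2 of the silent locus HMR, URA3 and TDH3. Of 3962 promoters, 3 were higher and 16 lower in both backgrounds, against 1 and 1 in the crossed contrast. Of these 19, 12 lay in repeated sequence and 7 in the copy number segments above, with 6 in both and 6 in neither. In neither were INO2, an activator of phospholipid synthesis genes (log2 0.66 and 1.14), and the nuclear pore gene NUP82 (1.24 and 0.98), which were higher. Also in neither were RPI1 (−1.02 and −0.87), YIR043C (−1.42 and −3.86), the glycolytic gene TDH3 (−1.38 and −2.08) and URA3 (−0.66 and −1.18), which were lower. The YIR043C promoter held 14, 6, 63 and 4 dyads. It met the minimum mean of 20 dyads only through the rpd3 library, and the upper bound of its first ratio was −0.013. Dyads were lower beyond the URA3 and TDH3 promoters too: the URA3 coding sequence was at −0.74 and −1.32, and the 700 bp upstream of TDH3 at 0.907, 0.484, 1.07 and 0.293 times the genome mean, in the order of libraries used throughout. The TDH3 coding sequence was at −0.065 and −0.21. Copies of these sequences were not measured, so their number cannot be told apart from nucleosome occupancy upstream of TDH3. The URA3 coding sequence was at 6.51, 3.90, 7.03 and 2.83 times the genome mean. SIR1, SIR3, SIR4, HST1 and HST2 lay between 0.921 and 1.52 over the libraries. These values argue against occupancy of 1 copy alone at URA3. How much of its ratios comes from a number of copies that differs was not measured. INO2, NUP82, RPI1, YIR043C and the stretch upstream of TDH3 were chosen after their values were seen. URA3 falls under the naming rule, and so does TDH3 as a member of a list described below. Across promoters the 2 sir2 contrasts had a correlation of 0.067.

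Among promoters with at least 50 dyads, ranked by the rule, the highest were YER181C, BOI1, RAD50, SHE3, COA4, MSC3, PRP40, YGL204C, FAP1 and HUT1, between log2 0.38 and 0.77 in the first sir2 contrast and between 0.39 and 0.78 in the second. COA4 and MSC3 share a divergent promoter. The lowest were URA3, YFR057W, YLR031W, BCH1, YMR105W-A, GTO1, RCN1, PDC6, EAF6 and IRC16, between −0.66 and −0.32 and between −1.18 and −0.35. Only URA3 among these passed the thresholds. YFR057W, near an end of chromosome VI, was at −0.47 (−0.97 to 0.03) and −0.46 (−1.01 to 0.07). The count of 19 was 9 with identical reads collapsed and 33 with a window of 400 bp.

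In the rpd3 contrasts, 13 promoters were higher and 7 lower in both backgrounds. The lower ones included LSO1 (log2 −0.69 and −0.76) and the iron permease gene FTR1 (−1.18 and −1.77). The others were MRX19, CWC21, YHR033W, the microtubule-binding protein gene STU2 and LCL1. Among the higher ones were the mitotic exit kinase gene CDC15 (0.95 and 0.96), CTO1 (1.25 and 1.22), the sporulation gene CDA2 (0.90 and 0.82) and the photolyase gene PHR1 (1.01 and 0.76). The remaining higher promoters were those of TYC1, YIR042C, GYP8, UBP6, CUP1-1, SNO2, SNZ2, YOR012W and YPL113C, with 3 of the 20 in repeated sequence. Except for LSO1, and for CDA2 and PHR1 as members of lists described below, these names were chosen after their values were seen. The split depended on the scaling, since the median promoter was at 0.071 and 0.064: scaled by the median of ratios, 9 were higher and 11 lower. With identical reads collapsed the count was 2 instead of 20, and a window of 400 bp gave 34, of which 7 were among the 20. The 2 rpd3 contrasts had a correlation of 0.14 across promoters.

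Ranked by the rule, the highest rpd3 promoters were BNA1, YAP1, SET2, BIK1, LOA1, YEL073C, STE12, HBS1, FRM2 and PRP39, between 0.37 and 0.74 and between 0.38 and 0.71. None of them passed the thresholds. BNA1, of NAD synthesis, was at 0.53 (−0.08 to 1.16) and 0.71 (0.19 to 1.24). The oxidative stress factor gene YAP1 was at 0.50 and 0.67, and SET2, a histone methyltransferase gene, at 0.61 and 0.50. The lowest were LSO1, CSR2, YIL046W-A, EAR1, RIM8, ILV1, CST9, GTO1, MND1 and FAT3, between −0.69 and −0.43 and between −0.76 and −0.40. Of these, LSO1 passed. MND1 and CST9, both of meiotic recombination, were at −0.43 and −0.62, and at −0.50 and −0.45.

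**Figure D4:**
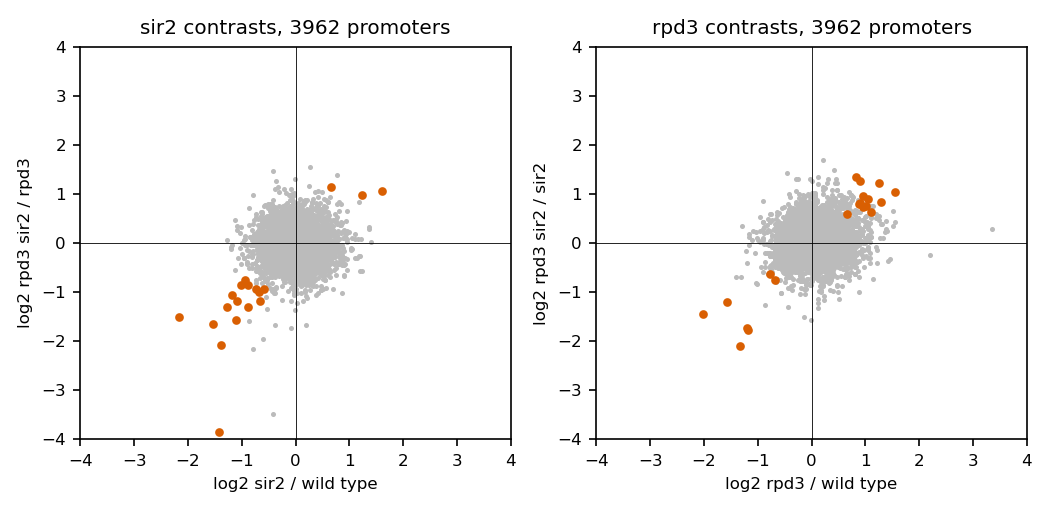
Points are 3962 promoters, with the log2 ratio in one background on the x axis and in the other on the y axis, for the sir2 contrasts (left) and the rpd3 contrasts (right). Orange points, 19 and 20, passed the thresholds in both backgrounds; the correlations across promoters are 0.067 and 0.14.

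Of the gene lists, metabolic targets of Ume6, the repressor that recruits Rpd3, stood apart in the rpd3 contrasts. Their median was −0.38, lower than in any of 10000 random lists. Of 7 measured members, 6 were lower in both backgrounds, among them ACS1 (mean log2 −0.52) and OPI3 (−0.44). POT1 was at −0.10, and PHR1, at 0.89, was higher past the thresholds. Early meiotic genes of the same pathway had a median of −0.074 at percentile 2.37, with 10 of 21 members lower and 3 higher in both backgrounds. MND1 (−0.52) and REC8 (−0.45) were lowest, and SPS19 (0.27) and MEI4 (0.19) highest. With the GC correction this percentile was 3.25, and without repeats and copy number segments 5.36, both inside the central 95%. Middle sporulation genes of the Sum1-Hst1 pathway had a median of 0.24 at percentile 97.8, with 8 of 15 members higher and 1 lower in both backgrounds. CDA2 (0.86) and SPO20 (0.54) were highest, and SPO75 (−0.48) and SSP2 (−0.02) lowest. With a window of 400 bp this list was at 87.4. Among 19 lists 0.95 would lie outside the central 95% by chance, and 3 did.

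In the sir2 contrasts 3 of 19 lists lay outside. Alpha-specific genes had a median of −0.43 at percentile 1.02 over 3 members: the pheromone genes MF(ALPHA)1 (−0.48) and MF(ALPHA)2 (−0.43) and the agglutinin gene SAG1 (0.20). Glycolytic genes had a median of −0.27 at percentile 1.35 over the 7 of 19 members measured. TDH3 (−1.73) and ADH1 (−0.68) were lowest and ENO1 (0.23) and TDH1 (0.025) highest. NAD and thiamine genes of the Sum1-Hst1 pathway had a median of 0.19 at percentile 98.9 over 12 members, of which 5 were higher and 1 lower in both backgrounds. BNA1 (0.31) and THI21 (0.28) were highest, and THI7 (−0.13) and THI73 (−0.09) lowest. With a window of 400 bp these 3 lists were at percentiles 7.90, 49.8 and 84.4, and the glycolytic median was 0.024. Early meiotic genes lay outside instead, at percentile 1.68. Of the silent mating loci, HMRA1 was at −2.17 and −1.51 and HMRA2 at −1.09 and −1.17 in the 2 sir2 contrasts. In the rpd3 contrasts HMRA1 was at −0.19 and 0.48 and HMRA2 at −0.19 and −0.27.

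The other lists lay inside the central 95% for that mutation. For both mutations, only members with a mean of at least 20 dyads were placed. These were 22 of 138 ribosomal protein genes and 23 of 53 ribosome biogenesis genes, so neither family was placed as a whole. In the sir2 contrasts, pheromone response genes were at a median of 0.16 (percentile 97.2), respiration and gluconeogenesis genes at 0.12 (94.8), ribosome biogenesis genes at 0.085 (85.0) and genes of the RPD3 and SIR complexes at 0.058 (78.8). Metabolic Ume6 targets were at 0.067 (75.2), middle sporulation genes at 0.059 (73.04), a-specific genes at 0.045 (61.9) and ribosomal protein genes at 0.0033 (44.9). Below 0 were galactose genes at −0.063 (27.3), G1 cyclins and DNA replication genes at −0.032 (25.6), stress response genes at −0.036 (18.4), early meiotic genes at −0.055 (14.7), phosphate genes at −0.13 (6.78) and subtelomeric sugar and flocculation families at −0.11 (3.71). Haploid-specific genes were at −0.076 (22.7), although their medians in the 2 backgrounds were 0.086 and 0.16.

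In the rpd3 contrasts, pheromone response genes were at 0.26 (97.0), a-specific genes at 0.20 (86.2), haploid-specific genes at 0.18 (82.3), respiration and gluconeogenesis genes at 0.15 (81.8) and alpha-specific genes at 0.19 (69.3). NAD and thiamine genes were at 0.089 (60.2), glycolytic genes at 0.14 (58.1), ribosomal protein genes at 0.086 (55.9) and G1 cyclins and DNA replication genes at 0.067 (45.9). Galactose genes were at 0.0092 (33.8), stress response genes at 0.037 (33.6), phosphate genes at −0.027 (18.7), genes of the RPD3 and SIR complexes at −0.0089 (16.4), subtelomeric families at −0.025 (10.5) and ribosome biogenesis genes at −0.037 (4.19). With a window of 400 bp, pheromone response, a-specific and NAD and thiamine genes lay outside, at percentiles 99.9, 99.1 and 99.8.

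The silent mating loci were compared because Sir2 silences them. At HMR (chromosome III, 292388 to 295034), reads of mapping quality 10 or more gave 304 dyads in wild type, 234 in the library labelled sir2, 329 in rpd3 and 228 in the library labelled rpd3 sir2. The log2 ratios were −0.64 (−0.90 to −0.39) and −0.58 (−0.83 to −0.33) in the sir2 contrasts. The difference was largest between the a2 and a1 genes, their shared promoter (293539 to 293834), with 32, 5, 30 and 9 dyads. There the log2 ratios were −2.83 (−4.66 to −1.57) and −1.74 (−3.05 to −0.68). Over the a1 gene they were −0.19 (−0.52 to 0.14) and −0.52 (−0.86 to −0.19). Outside the a1 gene they were −1.31 (−1.74 to −0.90) and −0.65 (−1.03 to −0.28). The rpd3 contrasts over HMR were 0.19 (−0.04 to 0.42) and 0.25 (−0.02 to 0.52), and outside the a1 gene 0.094 (−0.24 to 0.43) and 0.75 (0.31 to 1.21). HML could not be compared, as its flank held 0 and 3 dyads in the libraries labelled sir2 and rpd3 sir2. The first 300 bp of the alpha1 gene, over the HML and MAT copies together, held 97, 0, 115 and 3 dyads. The libraries labelled sir2 thus held almost no alpha1 reads at the mating locus MAT either, where the reference has the alpha genes. Reads of a genes at MAT would be placed on HMR, so the HMR values above may mix both loci in any of the libraries.

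Dyads next to chromosome ends were lower in the sir2 contrasts and higher in the rpd3 contrasts. In the first 2 kb, outside the copy number segments, dyads were lower at log2 −0.31 (−0.37 to −0.24) and −0.40 (−0.46 to −0.33) in the sir2 contrasts. They were higher at 0.20 (0.13 to 0.26) and 0.11 (0.04 to 0.18) in the rpd3 contrasts. Farther in, the sir2 contrasts varied: −0.015 (−0.073 to 0.043) and −0.091 (−0.15 to −0.033) from 4 to 6 kb, −0.11 and −0.25 from 6 to 8 kb, and 0.068 (0.029 to 0.11) and 0.036 (−0.0040 to 0.077) from 12 to 14 kb. The rpd3 contrasts were still at 0.14 (0.10 to 0.18) and 0.11 (0.072 to 0.15) from 12 to 14 kb. Over the 20 kb next to all 32 ends, the sir2 contrasts were at −0.0037 (−0.017 to 0.0093) and −0.040 (−0.053 to −0.027), and 26 and 29 ends were below 0. The rpd3 contrasts were at 0.11 (0.098 to 0.12) and 0.075 (0.062 to 0.088), with 5 and 3 ends below 0. With the ends in copy number segments left out, the first sir2 contrast was −0.029 and the second −0.075. The median of 70 promoters within 20 kb was 0.022 and −0.042 in the sir2 contrasts, against 0.0076 and 0.021 for other promoters. In the rpd3 contrasts it was 0.17 and 0.12, against 0.071 and 0.064.

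Replication origins were compared because the series concerns the replication program. Over the central 200 bp of 350 annotated origins outside the rDNA, dyad density was 0.335 times the genome mean in wild type, 0.322 in the library labelled sir2, 0.374 in rpd3 and 0.359 in the library labelled rpd3 sir2. Summed over origins, the rpd3 contrasts were higher at log2 0.16 (0.11 to 0.20) and 0.15 (0.11 to 0.20). Part of this sum came from ARS810 and ARS811: without them, as chosen after the data were seen, it was 0.098 and 0.11. The median origin was at 0.071 and 0.11, close to the median promoter at 0.071 and 0.064. The sir2 contrasts were lower at −0.058 (−0.11 to −0.011) and −0.059 (−0.11 to −0.012). With the 124 origins of at least 20 dyads, a minimum added after the data were seen, the second sir2 contrast was 0.0050. Single origins were ranked only among the 24 with a mean of at least 50 dyads. The highest of these in the rpd3 contrasts were ARS811 (1.41 and 1.38) and ARS810 (1.31 and 0.89), both in the CUP1 array of chromosome VIII, and ARS103 (0.29 and 0.57). The lowest were ARS310 (−0.25 and −0.62), ARS910 (−0.19 and −0.31) and ARS1512 (−0.36 and −0.19). In the sir2 contrasts ARS103, which lies in a copy number segment (0.89 and 1.17), ARS1425 (0.53 and 0.44) and ARS1219 (0.31 and 0.23) were highest. ARS212 (−0.59 and −0.30), ARS1207 (−0.24 and −0.41) and ARS801 (−0.55 and −0.21) were lowest.

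By their medians, early and late origins did not stand apart from random lists of origins at this depth. The 21 early origins had medians of −0.18 (percentile 12.8) in the sir2 contrasts and 0.20 (72.1) in the rpd3 contrasts. The 20 late or dormant origins had medians of 0.039 (87.4) and −0.017 (8.13), although their medians in the 2 backgrounds were −0.13 and −0.042 for sir2 and 0.071 and 0.035 for rpd3. Summed over late or dormant origins, the sir2 contrasts were at −0.11 (−0.38 to 0.16) and −0.38 (−0.66 to −0.10), below 0 where the median was above it. Their mean was 12.2 and 11.3 dyads per library, and the window mattered: early origins in the rpd3 contrasts were at −0.19 (2.69) with 100 bp, and late origins in the sir2 contrasts at −0.14 (1.62) with 400 bp. Read coverage was also compared, since early replicating DNA has more copies in growing cells. The log2 ratio of reads summed over 1-kb bins near early origins, less that near late or dormant origins, was −0.0023 (−0.027 to 0.023) and 0.014 (−0.013 to 0.041) in the sir2 contrasts. In the rpd3 contrasts it was −0.012 (−0.039 to 0.014) and 0.0043 (−0.021 to 0.030). The result depended on the summary: averaging the ratios of bins, an alternative added after the data were seen, gave 0.030 and 0.043 in the sir2 contrasts, so a small difference in either direction stays open.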

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

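The tests of digestion and GC content at the NTS1 stretch were set before their results were seen, and all other tests here were chosen after. The URA3 coding sequence had rpd3 ratios of opposite sign in the 2 backgrounds, at log2 0.1124 in rpd3 over wild type and −0.4637 in the library labelled rpd3 sir2 over that labelled sir2; this difference was not tested. Mitochondrial reads, which no comparison used, were 3.67-fold (3.44 to 3.91) more frequent in the library labelled sir2 than in wild type, at 0.109% against 0.0298%, while rpd3 and the library labelled rpd3 sir2 held 0.0297% and 0.0314%.

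SIR2 was fully covered in the 2 libraries labelled sir2. A swap of labels among the 4 libraries was argued against if sir2 stands for a deletion, since another library would then lack SIR2. All 4 held it, at 0.947, 0.943, 0.986 and 0.857 times the genome mean in the order used throughout. A swap involving an allele that keeps the sequence would not show in SIR2 reads. DNA of a SIR2 strain that carries the stretch beside HML, such as this wild type, could also have been mixed into both libraries. This was argued against, since the stretch held at most 1.55% of the wild type level there. DNA of a SIR2 strain that lacks this stretch would not show in it, so such a mixture stays open. An allele that leaves the coding sequence in place, such as a base change, stays open: the lowest SIR2 density of the 2 libraries was 85.7% of the genome mean, and read positions do not show base changes. Whether Sir2 was lost from these cells was not measured.

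The NTS1 stretch held fewer dyads in the 2 libraries labelled sir2. A difference in digestion or library making across the genome was argued against, since 0.00298% of 350-bp windows outside the rDNA (1 of 33593) were as low in both sir2 contrasts. A GC bias was argued against, since the higher of the 2 ratios was still −2.73 after correction. Repeats that lack this sequence cannot be told apart from nucleosome loss, because no undigested DNA was analysed here: the stretch was at 0.0747 times the repeat mean in the library labelled sir2. A role of the sir2 genotype may also account for it and stays untested, given the SIR2 reads.

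HMR held fewer dyads in the 2 libraries labelled sir2. Reads shared with HML were argued against, since with reads of mapping quality 10 or more the higher upper bound of the 2 log2 ratios was −0.333. A deletion of HMR could not be excluded. Its sequence outside the a1 gene kept at least 40.3% of the wild type level, but reads of a genes at MAT would be placed there too. A loss of silencing in these cells may account for the difference, as a hypothesis that 1 library per genotype leaves untested.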

How the results depend on the processing

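The alternatives with a dyad offset of 67 bp, without repeats or copy number segments, with a minimum for origins, without the CUP1 array origins and with averaged bin ratios were chosen after the data were seen. Of 164 alternative values of the main results, 127 lay within the interval of the reported value or within 1.5 times the count. The interval came from the counts, from resampled genes, from the bins for correlations, or from random lists for early and late origins. A change of direction was checked for part of these values only. Of 114 alternative list medians, 112 lay nearer to the reported median than 0.5 times the width of the range of random lists. The others follow, and where no reason is given the cause was not tested. With identical reads collapsed, the rDNA share was 1.098%, 0.9246%, 1.116% and 1.014%, which follows from construction, since an array read on 2 reference copies has few distinct positions, and the depleted region of the library labelled sir2 was 0.3341. Promoters counted in the sir2 contrasts, 19 as reported, were 33 with 400 bp, 7 from −150 to −51, 2 with a minimum of 100 dyads, 9 with identical reads collapsed and 6 without repeats and copy number segments. In the rpd3 contrasts the 20 became 34, 4, 1 and 2 under the first 4 of these and 33 with no minimum. Fewer promoters were usable from −150 to −51 (1257) and with 100 dyads (35). With 400 bp, 5 lists lay outside for rpd3, the glycolytic median in the sir2 contrasts turned to 0.02398, and that of haploid-specific genes was 0.1537. Chromosome ends within 10 kb were at −0.0282 and −0.1046 in the sir2 contrasts and 0.1785 and 0.1022 in the rpd3 contrasts; within 30 kb, the second sir2 contrast was −0.01989 and the rpd3 contrasts 0.07749 and 0.06009; without copy number segments the sir2 contrasts were −0.02861 and −0.07513. All origins were at −0.1219 (second sir2 contrast) and 0.2403 (rpd3 over wild type) with 100 bp, at 0.09788 and 0.08315 in the rpd3 contrasts with 400 bp, and, with at least 20 dyads, at 0.005043 in the second sir2 contrast; without the CUP1 array origins, rpd3 over wild type was 0.09812. Early origins in the rpd3 contrasts were −0.1886 with 100 bp; late origins were 0.2356 with at least 20 dyads, which left 3. The difference between early and late coverage was 0.03003 and 0.04274 in the sir2 contrasts with the GC correction, which also averages bin ratios instead of summing reads; averaging alone gave 0.02998 and 0.04297, so the change came from averaging and not from GC content.

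No paired test was run. Each genotype has 1 library, so the only spread left would be that between the 2 backgrounds, which is no measure of replicate error. The 2 backgrounds were set side by side instead. The alternative based on scores of rDNA positions was not run, as the lists hold no scores, and the sum over all origins has no GC alternative. Depth limits promoters: at 57.7 dyads per 200 bp in wild type, most 1.5-fold changes were missed in simulated data.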

Other observations

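All values here come from a scan and comparisons chosen after the data were seen. Of 21564 windows of 500 bp, 8 were higher and 29 lower in both rpd3 contrasts; the lower windows include those of the deleted RPD3 gene. The highest lay upstream of TEC1, a filamentation regulator (chromosome II, 408501 to 409000, log2 1.54 and 1.41), and between GYP8 and STE2, the alpha-factor receptor gene (chromosome VI, 82001 to 82500, 1.68 and 1.298), where it overlaps the GYP8 promoter counted as higher above. Lower windows lay at FTR1 (−1.16 and −1.42), at PDR8 (−0.91 and −0.98), upstream of HIS4 (−0.88 and −1.42), INO1 (−0.94 and −0.72) and PHO5 (−0.68 and −0.61), and upstream of the meiotic gene RIM4 (−0.91 and −0.65). In the TOP3 gene a window (chromosome XII, 611001 to 611500) was at −1.77 and −0.97.

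In the sir2 contrasts 11 of these windows were higher and 4 lower. Most lay at the marker genes HIS3, LEU2 and URA3. Others were upstream of ILV5 (0.78 and 0.76), upstream of TEC1 (0.75 and 0.62) and at AAC1 (0.70 and 0.59), and lower at the left end of chromosome III (1501 to 2000, −0.89 and −0.92). Log2 ratios of the 2 backgrounds had a correlation across windows of 0.26 in the rpd3 contrasts and 0.026 in the sir2 contrasts.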
